A study of Mus musculus with 24 samples.

How the data were processed

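RNA sequencing libraries of C2C12 cells and of mouse brown adipose tissue were compared, 24 in all, of which 18 were from C2C12 cells and 6 from tissue. RNA was extracted with Trizol and RNeasy columns and made into stranded libraries with the TruSeq mRNA kit, per the labels. The deposited values are FPKM, 1 table per library, made by the authors with TopHat and Cufflinks on mm9, per the submitters' processing notes. Versions of both programs and the gene annotation are not given in the sources used here. Read totals are not given either, so the depth of a library and the counting error of a value are unknown.

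Each table lists 37305 genes. Entries of the same symbol with overlapping loci were summed, which merged 264 and left 37041 genes. Starts of loci in the tables count from 0, checked on the mitochondrial genes against GENCODE M21, and 1 was added to each. GENCODE M21 served only for the class of a gene, and 32488 gene IDs matched it. Some abundant genes are listed at 0 in single libraries. A value of 0 was called unlikely to be low expression where another library of the group had at least 100 FPKM and the gene is not a short RNA, or where the gene is a mitochondrially encoded mRNA, and these zeros were set to missing in an alternative. In the tissue tables, 11 or 12 of the 13 mitochondrially encoded mRNAs are listed at 0.

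Groups follow the labels: control and NFIA-expressing C2C12 cells at day 0, day 7 and day 7 with forskolin, and wild-type and NFIA-KO tissue, 3 libraries each. Values were compared as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with moderated two-sided tests and a variance trend. A fit of the 18 C2C12 libraries and another of the 6 tissue libraries were made. Genes with FPKM of at least 1 in at least 3 libraries of the fit were tested, 14351 in C2C12 cells and 13618 in tissue. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Interaction terms tested whether the NFIA effect differed between days and whether the forskolin response differed between NFIA and control cells.

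A total of 24 gene lists were fixed before the data were examined, together with the comparisons, the tests, the alternatives and the rule for naming genes. The lists cover the NFI family, brown adipocyte, general adipocyte and white adipose selective genes, adipogenic and myogenic regulators, skeletal muscle contractile genes, oxidative phosphorylation, fatty acid oxidation, lipogenesis, cholesterol biosynthesis, glycolysis, cell cycle, cAMP response, extracellular matrix, interferon response and stress response. They also cover markers of immune, endothelial and erythroid cells, nerve and glia, smooth muscle and pericytes, epidermis and adipocyte progenitors. Some lists share members, so their calls are not independent. Retn and Lep are in the general adipocyte and white adipose selective lists, and Pparg and Cebpa in the general adipocyte and adipogenic regulator lists. Lists with at least 5 tested members were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with an estimated correlation and with fry. Overlaps of called genes were tested with Fisher's exact test, two-sided, over genes tested in both fits.

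The rule named 9 genes in each main comparison (Nfia, Ucp1, Cidea, Ppargc1a, Pparg, Adipoq, Fabp4, Myod1 and Myog), of which Cidea, Adipoq and Myod1 were left out in the others. From each list that was called or had at least 3 called members it allowed up to 4 called members with the largest change, or up to 3 in the other comparisons. From other lists it allowed none, or up to 2 with the highest mean FPKM where the list is described. It also allowed the 5 genes per direction with the largest change, or 3 in the other comparisons, at a mean of at least 5 FPKM in the higher group. List members and largest genes had to have library values that did not overlap between groups. The text prints part of the genes the rule allows.

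The alternatives were a pseudocount of 0.1, no expression filter, quantile normalization, median-of-ratios rescaling, no variance trend, a 2-fold minimum, only the groups compared, a replicate block, only the C2C12 libraries with a number in their title, and each library left out in turn. Run date as a term, zeros as missing, protein-coding genes only, and the mean log2 level of the contractile list as a term in tissue were chosen after seeing the data. Dates in the column headers are earlier for the C2C12 libraries without a number and all tissue libraries, and later for the numbered C2C12 libraries. They are taken here as the dates of an earlier and a later run, which the sample labels do not state.

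The procedure was tested on simulated data, with independent normal noise at the fitted spread of each gene. At the size of the day 7 comparison it recovered 27 of 67 genes shifted by 0.5 log2 units, 54 of 67 shifted by 1 and 60 of 66 shifted by 2. At the size of the tissue comparison it recovered 1 of 67, 36 of 67 and 62 of 66, so changes of 0.5 were mostly missed there. False calls numbered 10 and 4. The simulated data held no outlying library and no correlation between genes. Far fewer genes were shifted than were called in the real comparisons, so these rates need not hold for them. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.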

Results

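Gene expression was measured by RNA sequencing in 24 libraries that form 8 groups of 3. C2C12 cells, a mouse myoblast line that forms muscle fibres in culture, were sequenced as control cells and as cells expressing NFIA, a transcription factor of the nuclear factor I family. Cells of both kinds were taken at day 0, at day 7, and at day 7 after 4 h with 10 µM forskolin, a compound that activates adenylyl cyclase and thereby raises cAMP. Brown adipose tissue of mouse neonates was sequenced in 3 wild-type libraries and in 3 libraries labelled NFIA-KO. The series title names NFIA, the adipocyte transcription factor PPARgamma and the brown fat gene program, so the comparisons ask which adipocyte, brown fat and muscle genes move when NFIA is added to myoblasts or lost from brown fat.

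The tables give FPKM (fragments scaled to transcript length and to the mapped fragments of the library) for 37041 genes after 264 entries had been merged into another of the same symbol with an overlapping locus. FPKM sums per library ran from 762822 to 1575522, and the number of genes above 0 from 17370 to 21503. Read totals are not given in the sources used here, so the depth behind each value is unknown. A short RNA entry, mmu-mir-703, alone held 29085 to 393312 FPKM per C2C12 library and 0 to 24100.3 per tissue library. In the C2C12 cells, 53.0% of the variance of protein-coding genes lay on the leading principal component, which set the day 7 NFIA cells, with or without forskolin, apart from the other 12 libraries. Group values below are means of FPKM ± SD over 3 libraries, and differences are log2 fold changes of FPKM + 1 with their SE. Such folds understate changes of genes with low FPKM. For each named gene that passed between groups, the 3 libraries of one group all lay above the 3 of the other. Chance gives this in 10% of genes, and the rule for naming list members and largest genes required it, so it is no added support.

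Nfia itself (ENSMUSG00000028565.11, protein-coding, mm9 chromosome 4, 97234824 to 97868605) was near 0 in control cells and high in every NFIA library. It read 0.660 ± 0.465 FPKM in control cells and 1269 ± 15.6 in NFIA cells at day 0. At day 7 it read 1.33 ± 0.785 against 3343 ± 212, and with forskolin 1.57 ± 0.250 against 9852 ± 608. Its difference between NFIA and control cells was larger at day 7 than at day 0 (interaction 0.92 ± 0.28; adjusted p = 0.015) and larger with forskolin than without (interaction 1.37 ± 0.28; adjusted p = 0.0029). Within NFIA cells Nfia rose by 1.56 ± 0.20 with forskolin. The other key genes were Ucp1 (ENSMUSG00000031710.3, chromosome 8, 85814247 to 85822355), Pparg (ENSMUSG00000000440.6, chromosome 6, 115311239 to 115440419), Adipoq (ENSMUSG00000022878.5, chromosome 16, 23146609 to 23158101) and Ppargc1a (ENSMUSG00000029167.7, chromosome 5, 51845488 to 51958964). Among muscle genes they were Myog (ENSMUSG00000026459.4, chromosome 1, 136186581 to 136189124) and Ckm (ENSMUSG00000030399.1, chromosome 7, 19996443 to 20006932). All 7 genes are protein-coding in GENCODE M21, and a listed locus can span overlapping genes.

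**Figure D1:**
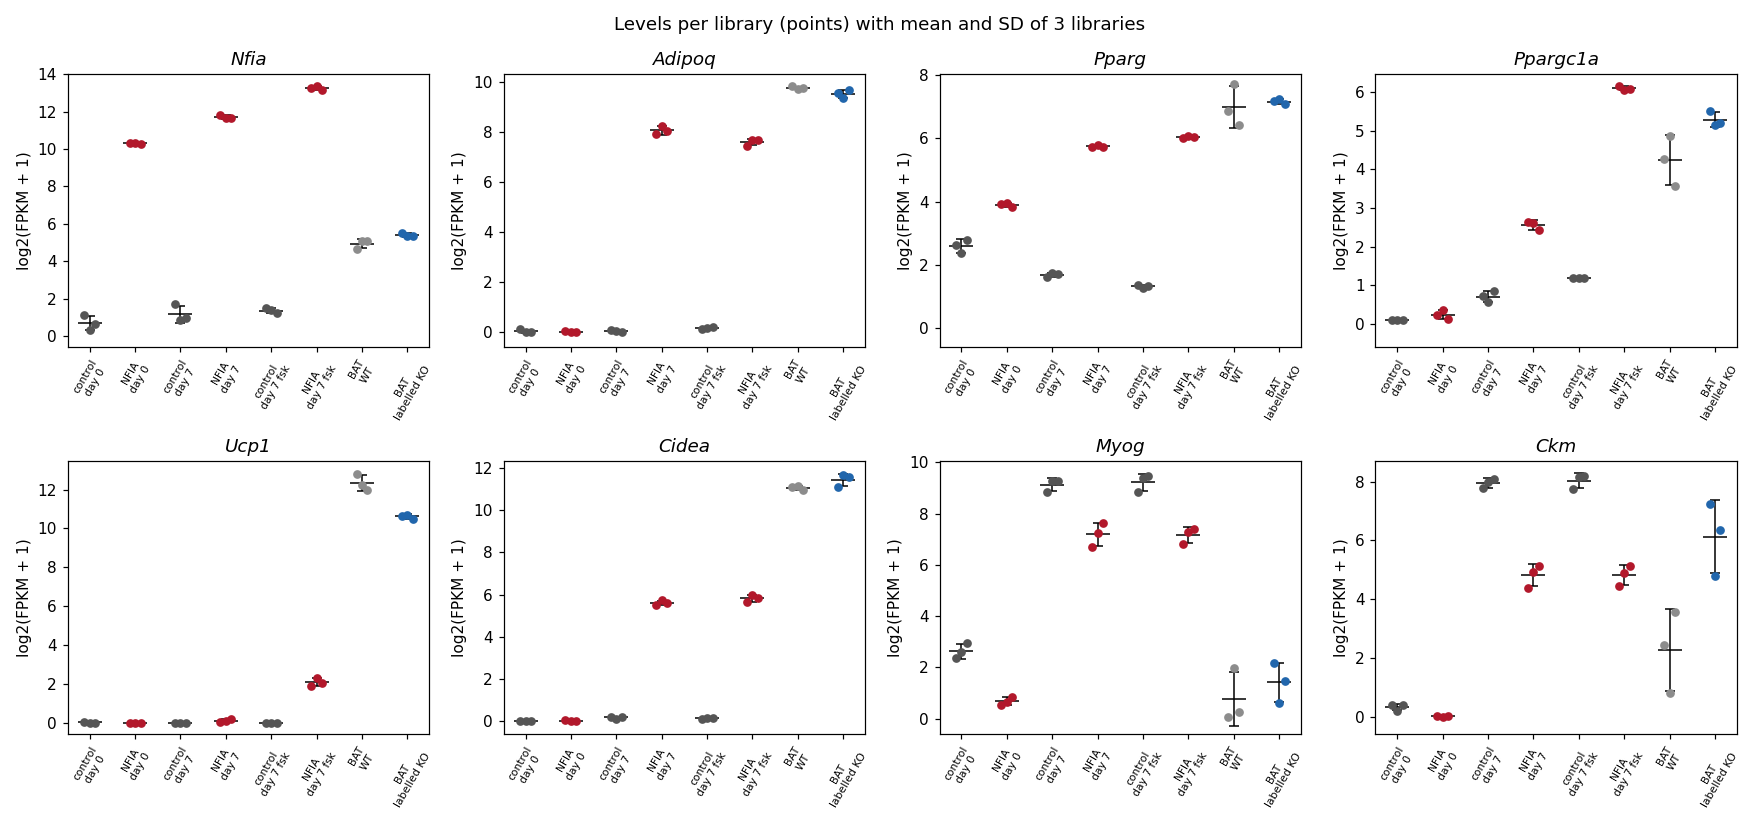
Level of 8 genes as log2(FPKM + 1), each point a library, with the mean and SD of the 3 libraries per group for all 8 groups. Adipoq averaged 266 FPKM in day 7 NFIA cells and 0.0333 in day 7 control cells, while Ucp1 averaged 5355 FPKM in wild-type tissue and 1571 in the libraries labelled NFIA-KO.

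At day 0, which shows the effect of NFIA at the earlier time point, interferon-response, extracellular matrix and adipocyte progenitor genes were higher in NFIA cells and myogenic genes were lower. Pparg, the master regulator of fat cell formation, rose from 5.10 ± 0.852 to 14.0 ± 0.685 FPKM (1.30 ± 0.09; adjusted p = 2.1e-08). Lpl, which releases fatty acids from lipoproteins, rose from 9.64 ± 0.485 to 124 ± 10.6. Adipoq and Cidea stayed below 0.03 FPKM on average in both groups, and their differences did not pass. Fabp4, a fatty acid carrier of adipocytes, read 6.18 ± 2.11 against 2.26 ± 1.76 (1.23 ± 0.38; adjusted p = 0.033). The Fabp4 call ended without NFIA replicate 1 or 2, or without control replicate 2 or 3.

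Interferon-response genes rose together at day 0: 14 of 16 tested were higher and 0 lower, 16 when adjusted over the list alone, with a median log2 fold change of 0.92 (adjusted p = 1.3e-12). Ifit1, an antiviral RNA-binding protein, rose from 2.50 ± 0.338 to 22.1 ± 1.25 FPKM, and Isg15, a ubiquitin-like modifier, from 5.81 ± 2.01 to 31.3 ± 4.78. Of 28 matrix genes, 18 were higher and 5 lower (19 and 5 adjusted over the list alone; median 0.66; adjusted p = 8.6e-08). Elastin (Eln) rose by 5.20 ± 0.13 and periostin (Postn) by 3.24 ± 0.16. Of 6 progenitor markers, 5 were higher and 0 lower, in the list alone too (median 1.39; adjusted p = 1.1e-05). The stem cell antigen Cd34 rose by 2.73 ± 0.09 and the growth factor receptor Pdgfra by 1.65 ± 0.13. Cholesterol biosynthesis genes were higher in 15 of 19 cases and lower in 0 (16 adjusted over the list alone; median 0.45; adjusted p = 7.0e-07), among them the sterol sensor Insig1 (0.88 ± 0.06). These 4 calls held with an estimated correlation.

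Myogenic regulators and contractile genes were lower at day 0. Of 14 regulators, 7 were lower and 1 higher (8 and 1 adjusted over the list alone; median -0.44; adjusted p = 6.3e-05), a call that held with an estimated correlation. Myog, which drives myoblasts into terminal differentiation, fell by 1.95 ± 0.24 and Myf5, an earlier myogenic factor, by 2.39 ± 0.08. Myod1 read 12.01 ± 0.609 against 16.03 ± 2.83 FPKM and did not pass (adjusted p = 0.27). Of 37 contractile genes, 18 were lower and 2 higher (20 and 2 in the list alone; median -0.45; adjusted p = 8.6e-08, and adjusted p = 0.093 with an estimated correlation). Alpha-actinin 3 (Actn3) fell by 2.19 ± 0.10, while troponin C2 (Tnnc2) rose by 2.72 ± 0.20.

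A further 6 lists were called higher at day 0, and each call was lost with an estimated correlation. General adipocyte genes had 9 higher and 1 lower of 22, the same in the list alone (median 0.03; adjusted p = 0.0051, and adjusted p = 0.37 with an estimated correlation). The lipid droplet protein Plin4 rose by 2.01 ± 0.07 and carbonic anhydrase 3 (Car3) fell by 3.88 ± 0.12. Adipogenic regulators had 9 higher and 2 lower of 14 (median 0.83; adjusted p = 0.0018, and adjusted p = 0.078 with an estimated correlation), among them Cebpa (1.52 ± 0.25). White adipose selective genes had 4 higher of 6 (adjusted p = 0.0016, and adjusted p = 0.059 with an estimated correlation), among them angiotensinogen (Agt; 2.56 ± 0.09). The cAMP-response list had 11 higher and 1 lower of 21 (adjusted p = 3.3e-05, and adjusted p = 0.078 with an estimated correlation), and the stress-response list 9 higher of 14 (adjusted p = 8.6e-08, and adjusted p = 0.078 with an estimated correlation). Immune cell markers, with 2 higher of 5, were the last of them (adjusted p = 0.029, and adjusted p = 0.093 with an estimated correlation). Brown adipocyte genes showed no call, with 0 of 15 past the threshold (median -0.05; adjusted p = 0.38).

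Outside the lists, the largest changes at day 0 included the secreted Wnt modulator Sfrp2, which rose by 5.49 ± 0.13 to 587 ± 59.7 FPKM, and the angiopoietin Angpt4, which rose by 5.17 ± 0.15. Among the largest decreases were the proliferin genes Prl2c2 and Prl2c3, which fell by 4.44 ± 0.36 and 4.29 ± 0.20. In limma, 3036 of 14351 genes passed at day 0, 1735 higher and 1301 lower (1617 and 1553 under quantile normalization). The numbered libraries alone, all from a later run, gave 3997, run date as a term 5303, a replicate block 5159 and the 6 libraries compared alone 1872. The earlier run holds 1 C2C12 library per group, so it gives no value of its own for any C2C12 comparison.

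By day 7, NFIA cells expressed adipocyte genes at high levels and muscle genes at reduced levels relative to control cells. Fabp4 reached 22388 ± 1058 FPKM in NFIA cells against 4.30 ± 2.52 in control cells. Adipoq, which encodes the hormone adiponectin, reached 266 ± 31.2 against 0.0333 ± 0.0351, a change of 8.01 ± 0.08. Pparg rose from 2.22 ± 0.162 to 52.7 ± 1.13 (4.06 ± 0.09; adjusted p = 1.0e-14). Of 22 general adipocyte genes, 21 were higher and 1 lower, in the list alone too (median 5.08; adjusted p = 3.7e-18), a call that held with an estimated correlation. The lipid droplet proteins Cidec and Plin1 reached 402 ± 47.0 and 329 ± 47.9 FPKM. Of 14 adipogenic regulators, 12 were higher and 1 lower, in the list alone too (median 2.17; adjusted p = 6.8e-06), which also held. Cebpa, a partner of PPARgamma, rose from 5.77 ± 0.951 to 144 ± 34.3 and the glucocorticoid-induced factor Klf15 by 5.33 ± 0.12.

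Brown adipocyte genes were a mixed group at day 7: 9 of 15 were higher and 3 lower (9 and 4 adjusted over the list alone; median 0.80; adjusted p = 0.012, and adjusted p = 0.11 with an estimated correlation). Cidea, a lipid droplet protein abundant in brown fat, rose to 48.0 ± 3.68 FPKM from 0.140 ± 0.0361, and Ppargc1a, a coactivator that drives mitochondrial biogenesis, to 4.89 ± 0.489 from 0.640 ± 0.150. Cox8b, a muscle and brown fat subunit of cytochrome oxidase, rose by 2.31 ± 0.34. Ucp1, the uncoupling protein that produces heat in brown fat, read 0.0633 ± 0.0611 in NFIA cells and was listed at 0 in all control libraries. White adipose selective genes had 4 higher and 1 lower of 6, the same in the list alone (adjusted p = 0.019, and adjusted p = 0.11 with an estimated correlation). Among them were resistin (Retn; 6.77 ± 0.11), which the general adipocyte list also holds, and Agt (5.67 ± 0.09).

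Lipid metabolism genes rose at day 7 in NFIA cells. Of 14 lipogenesis genes, 13 were higher and 0 lower, in the list alone too (median 2.40; adjusted p = 1.3e-09), a call that held with an estimated correlation. Fatty acid synthase (Fasn) rose from 31.4 ± 0.413 to 958 ± 106 FPKM. Stearoyl-CoA desaturase 1 (Scd1) was listed at 0 in 2 of the 3 day 7 NFIA libraries and at 4056 in replicate 3, so no fold is given for it; it was chosen after its values were seen. Of 22 fatty acid oxidation genes, 19 were higher and 0 lower (20 in the list alone; median 0.94; adjusted p = 2.1e-09, and adjusted p = 0.074 with an estimated correlation). The mitochondrial dehydrogenase Acadm rose by 2.65 ± 0.06. Oxidative phosphorylation genes had 10 higher and 0 lower of 70 (6 in the list alone; median 0.31; adjusted p = 0.029, and adjusted p = 0.69 with an estimated correlation). That call ended without control replicate 1 (adjusted p = 0.16) or NFIA replicates 2 (adjusted p = 0.083) or 3 (adjusted p = 0.054).

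All 37 contractile genes were lower in NFIA cells at day 7, in the list alone too (median -2.92; adjusted p = 9.2e-20). Myosin light chain 4 (Myl4) fell by 4.99 ± 0.27, from 2397 ± 526 to 74.7 ± 15.9 FPKM, and troponin T1 (Tnnt1) by 3.89 ± 0.11. Of 14 myogenic regulators, 12 were lower and 1 higher, in the list alone too (median -1.34; adjusted p = 1.7e-04). Myog fell by 1.94 ± 0.24 to 149.5 ± 46.0 FPKM, Mef2c, a cofactor of the myogenic factors, by 4.29 ± 0.14, and Myod1 by 1.04 ± 0.21. Matrix genes had 23 lower and 4 higher of 28, in the list alone too (median -2.37; adjusted p = 8.1e-09). The collagens Col1a1 and Col3a1 fell by 5.49 ± 0.15 and 3.93 ± 0.08. These 3 calls held with an estimated correlation.

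Genes of dividing cells, smooth muscle markers and interferon-response genes were also lower at day 7. Cell cycle genes had 27 lower and 0 higher of 33 (27 lower and 1 higher in the list alone; median -1.43; adjusted p = 2.8e-08, and adjusted p = 0.11 with an estimated correlation), among them cyclin B2 (Ccnb2; -2.56 ± 0.16). Smooth muscle and pericyte markers had 5 lower and 1 higher of 6 (adjusted p = 0.0015, and adjusted p = 0.11 with an estimated correlation), among them transgelin (Tagln; -3.01 ± 0.12). Interferon-response genes had 9 lower and 1 higher of 16, in the list alone too (median -0.72; adjusted p = 0.032, and adjusted p = 0.081 with an estimated correlation), among them Ifit2 (-2.07 ± 0.12). The cAMP-response list, with 12 higher and 5 lower of 21, and the stress list, with 8 higher and 1 lower of 14, were called higher (adjusted p = 0.0058 and 0.029, and adjusted p = 0.19 and 0.44 with an estimated correlation). Lists without a call included cholesterol biosynthesis, with 8 higher and 7 lower of 19, and glycolysis, with 4 higher and 8 lower of 17 (adjusted p = 0.52 and 0.18).

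The effect of NFIA at day 7 differed from its effect at day 0 for 6505 of 14351 genes in the interaction test, 2843 with a positive and 3662 with a negative term (3452 and 3333 under quantile normalization). General adipocyte genes had positive terms in 21 of 22 cases (median 5.11; adjusted p = 3.3e-22), and matrix and interferon genes mostly negative ones, 26 of 28 (median -3.21; adjusted p = 1.1e-15) and 13 of 16 (median -1.81; adjusted p = 3.7e-06). Each of these 3 held with an estimated correlation. Among genes called at both days, 779 were higher at both (452.3 expected) and 833 lower at both (382.7 expected), while 521 were higher at day 0 and lower at day 7 (510.3 expected). The largest increases at day 7, besides Fabp4 and Nfia, were the cytochrome P450 gene Cyp2e1 (1088 ± 21.9 against 0.307 ± 0.215 FPKM), the retinol carrier Rbp4 and complement C3. Counts at day 7 were 3741 genes higher and 4221 lower (4184 and 4077 under quantile normalization), 7962 in all, and 9336 in the numbered libraries alone.

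With forskolin at day 7, a stimulus used to mimic cold activation of brown fat, the NFIA cells differed from control cells in 8845 genes, 4118 higher and 4727 lower (10003 in the numbered libraries alone). Adipocyte and muscle genes kept the directions seen without forskolin: 21 of 22 general adipocyte genes were higher (median 5.09; adjusted p = 2.8e-15) and all 37 contractile genes lower (median -2.91; adjusted p = 2.2e-17), and both calls held with an estimated correlation. Across genes, the log2 fold changes of NFIA against control with and without forskolin had a Pearson correlation of 0.858, though genes are not independent replicates. Of the brown adipocyte genes, 10 were higher and 3 lower of 15, in the list alone too (median 0.93; adjusted p = 0.0034, and adjusted p = 0.074 with an estimated correlation). Ppargc1a reached 67.4 ± 2.66 FPKM in NFIA cells and 1.28 ± 0.0115 in control cells, and Cidea 56.3 ± 6.57 and 0.11 ± 0.01. Ucp1 read 3.25 ± 0.623 in NFIA cells and was listed at 0 in all control libraries.

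Genes that respond to cAMP were higher in NFIA cells under forskolin. Of the 21 in the list, 20 were higher in NFIA cells and 0 lower (21 in the list alone; median 2.87; adjusted p = 6.6e-13), a call that held with an estimated correlation. Atf3, a stress-induced transcription factor, reached 723 ± 56.6 FPKM against 1.47 ± 0.292, and the orphan nuclear receptor Nr4a3 199.6 ± 20.9 against 0.980 ± 0.144. Stress-response genes had 11 higher of 14 (median 2.20; adjusted p = 1.4e-05, and adjusted p = 0.11 with an estimated correlation), among them heat shock protein Hspa1b (5.02 ± 0.24). Lipogenesis genes had 13 higher of 14 (adjusted p = 8.2e-08, held with an estimated correlation), among them Dgat1, which makes triglycerides (5.14 ± 0.12). Matrix genes had 20 lower and 6 higher of 28 (adjusted p = 1.5e-04, and adjusted p = 0.11 with an estimated correlation). In the NFI family, Nfic (-1.13 ± 0.12) and Nfix (-0.74 ± 0.10) were lower while Nfia was higher.

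**Figure D2:**
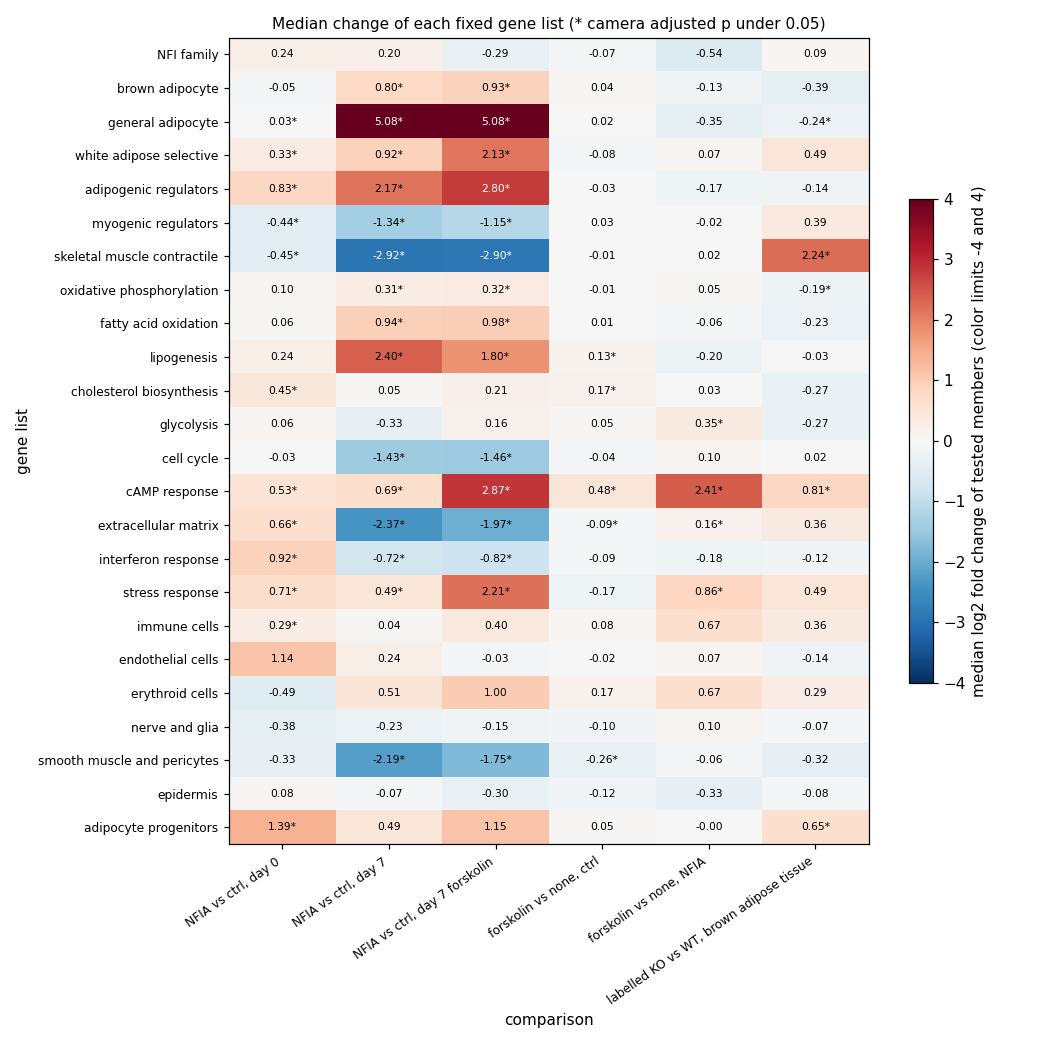
Median log2 fold change of FPKM + 1 for each fixed gene list in 6 comparisons, colour limits -4 and 4, with an asterisk where the camera adjusted p is under 0.05. The general adipocyte list reads 5.08 at day 7 and the contractile list -2.92, while in tissue the contractile list reads 2.24.

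Between day 0 and day 7, control cells turned on the muscle program, which is the usual fate of this line. All 37 contractile genes rose, in the list alone too (median 6.41; adjusted p = 3.0e-39), and 12 of 14 myogenic regulators rose with 0 lower (median 1.0; adjusted p = 1.3e-05), both held with an estimated correlation. Myog rose from 5.31 ± 1.28 to 565 ± 97.4 FPKM and Myl4 by 9.77 ± 0.27. Matrix genes rose in 20 of 28 cases and fell in 1 (median 1.11; adjusted p = 1.5e-09), and cholesterol biosynthesis genes fell in 17 of 19 and rose in 1 (median -1.04; adjusted p = 1.1e-08), both held. Cell cycle genes fell in 31 of 33 (adjusted p = 8.6e-11, and adjusted p = 0.14 with an estimated correlation), glycolysis genes rose in 15 of 17 (adjusted p = 1.2e-07, and adjusted p = 0.17 with an estimated correlation) and oxidative phosphorylation genes in 30 of 70 (adjusted p = 1.0e-04, and adjusted p = 0.69 with an estimated correlation). Pparg fell by 0.91 ± 0.09. General adipocyte genes, with 7 higher and 2 lower of 22, were not called (adjusted p = 0.14). In all, 7013 genes passed, 3579 higher and 3434 lower (8420 in the numbered libraries alone). Quantile normalization moved the median of all genes in this comparison from 0.02 to -0.11 and gave 2983 higher and 4541 lower.

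Over the same days, NFIA cells turned on adipocyte genes and, at a lower level, muscle genes. All 22 general adipocyte genes rose, in the list alone too (median 5.19; adjusted p = 1.3e-20), and all 37 contractile genes rose as well (median 3.54; adjusted p = 1.6e-22), both held with an estimated correlation. The rise of contractile genes was smaller than in control cells, with negative interaction terms past the threshold for 34 of 37 (median -2.15; adjusted p = 8.9e-16, held). Myog rose by 6.50 ± 0.24 in NFIA cells and by 6.49 ± 0.24 in control cells, and the interaction term was 0.01 (adjusted p = 0.99). Brown adipocyte genes rose in 8 of 15 cases with 0 lower (median 1.41; adjusted p = 1.4e-04, held), among them Cox8b (8.19 ± 0.34). Interferon-response genes fell in 14 of 16 and rose in 1 (adjusted p = 2.5e-06), matrix genes fell in 23 of 28 and rose in 3 (adjusted p = 2.8e-08), and cell cycle genes fell in all 33 (adjusted p = 6.4e-17), each held with an estimated correlation. The secreted Wnt modulator Sfrp2 fell by 6.12 ± 0.13. Counts were 8163 genes in all, 3948 higher and 4215 lower (9305 in the numbered libraries alone). Median-of-ratios rescaling gave 4293 higher and 4002 lower.

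In control cells at day 7, forskolin changed genes of the cAMP response. Of 21 cAMP-response genes, 11 were higher and 2 lower (12 and 2 in the list alone; median 0.48; adjusted p = 5.6e-12), a call that held with an estimated correlation. The phosphodiesterase Pde4b, which degrades cAMP, rose by 1.43 ± 0.09 and the nuclear receptor Nr4a2 by 1.5 ± 0.13, while the immediate early gene Egr1 fell by 1.5 ± 0.08. The neuropeptide Y receptor Npy1r rose by 3.08 ± 0.08 and the vitamin D receptor Vdr by 2.79 ± 0.17. Cholesterol biosynthesis genes had 4 higher of 19 (8 in the list alone; adjusted p = 4.2e-07, held with an estimated correlation). Matrix genes had 4 lower of 28, among them Ctgf (-2.19 ± 0.12), and smooth muscle markers 3 lower of 6 (adjusted p = 1.5e-04 and 9.6e-05, and adjusted p = 0.20 and 0.098 with an estimated correlation). Lipogenesis genes had 2 higher of 14 (adjusted p = 0.0029, and adjusted p = 0.083 with an estimated correlation). Counts were 570 genes, 275 higher and 295 lower (305 and 301 under quantile normalization). The count was 750 in the numbered libraries alone, 1343 with run date as a term, 1260 with a replicate block and 239 with the 6 libraries compared alone. Without control replicate 2 of the untreated or of the treated group, 363 and 361 genes passed.

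In NFIA cells forskolin changed 4681 genes, 2249 higher and 2432 lower (6612 in the numbered libraries alone). The split was 1775 higher and 2437 lower under quantile normalization, and 498 higher and 160 lower at a 2-fold minimum. Of 21 cAMP-response genes, 20 were higher and 0 lower, in the list alone too (median 2.41; adjusted p = 3.2e-28), a call that held with an estimated correlation. Nr4a3 rose from 1.10 ± 0.220 to 199.6 ± 20.9 FPKM and Nr4a1 from 8.62 ± 1.81 to 412 ± 59.1. Ppargc1a rose by 3.54 ± 0.08, Ucp1 by 1.99 ± 0.08 to 3.25 ± 0.623 FPKM, and Dio2, which activates thyroid hormone in brown fat, by 3.03 ± 0.09. The brown adipocyte list as a whole had 5 higher and 5 lower of 15 and was not called; its median was -0.13 and its mean 0.38 (adjusted p = 0.61). Stress-response genes rose in 11 of 14 cases (adjusted p = 7.1e-08, and adjusted p = 0.20 with an estimated correlation) and glycolysis genes in 8 of 17 (adjusted p = 3.1e-04, and adjusted p = 0.49 with an estimated correlation), among them the glucose transporter Slc2a1 (1.93 ± 0.18). G0s2, an inhibitor of lipolysis, fell by 2.34 ± 0.34. Matrix genes rose in 10 of 28 and fell in 1 (adjusted p = 0.025, and adjusted p = 0.49 with an estimated correlation), a call that ended without untreated NFIA replicate 3 (adjusted p = 0.069).

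The response to forskolin differed between NFIA and control cells for 2890 genes in the interaction test, 1511 with a positive and 1379 with a negative term (1165 and 1399 under quantile normalization). The count was 4556 in the numbered libraries alone, 5149 with run date as a term and 5041 with a replicate block. Of 21 cAMP-response genes, 18 had positive terms (20 in the list alone; median 2.14; adjusted p = 7.3e-26), a call that held with an estimated correlation. The interaction terms of Ppargc1a (3.06 ± 0.12) and Nr4a3 (5.97 ± 0.13) were positive, and Nr4a3 was chosen for this test after its values were seen. Of the genes called with forskolin, 165 were higher in both kinds of cell (43.1 expected) and 91 lower in both (50.0 expected). A further 77 were lower in control and higher in NFIA cells (46.2 expected), and 27 the reverse (46.6 expected).

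In brown adipose tissue, the Nfia level was read before any other gene. It was 24.3, 32.8 and 32.6 FPKM in the wild-type libraries and 44.6, 40.1 and 39.4 in the libraries labelled NFIA-KO (0.47 ± 0.15; adjusted p = 0.097), so the label is not visible as a lower Nfia value. A gene-level FPKM cannot separate an intact transcript, a partly deleted transcript and a wrong label, so each direction in tissue rests on the labels as given. The part of the gene that was targeted is not given in the sources used here. Ucp1 was 1571 ± 116 FPKM in the libraries labelled NFIA-KO and 5355 ± 1667 in wild-type tissue (-1.73 ± 0.21; adjusted p = 0.018). Cox8b was 882 ± 43.5 against 3776 ± 320.5 (-2.09 ± 0.11; adjusted p = 0.0012). Asparagine synthetase (Asns) fell by 1.90 ± 0.13 and the growth factor betacellulin (Btc) rose by 4.38 ± 0.34. These 4 genes kept their call without any library in turn.

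Brown adipocyte genes in tissue had 5 lower and 0 higher of 24 (11 and 3 in the list alone; median -0.39), and the list was not called (adjusted p = 0.073), except without wild-type replicate 3 (adjusted p = 0.043) or replicate 2 labelled NFIA-KO (adjusted p = 0.046). General adipocyte genes had 5 lower and 0 higher of 23 (9 and 0 in the list alone; median -0.24; adjusted p = 0.0094, and adjusted p = 0.755 with an estimated correlation). Adig, which is needed for fat cell formation, fell by 2.0 ± 0.17, and Cebpa by 2.06 ± 0.30. Adipoq read 735 ± 80.1 against 865 ± 26.5 FPKM and Pparg 142 ± 8.20 against 136 ± 64.4, and neither passed. Fabp4 was listed at 0 in wild-type replicate 3 and at 23064 and 21230 in the other wild-type libraries, so no fold is given for it. Oxidative phosphorylation genes had 5 lower and 0 higher of 70, in the list alone too (median -0.19; adjusted p = 2.5e-04, and adjusted p = 0.755 with an estimated correlation).

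Muscle genes were higher in the libraries labelled NFIA-KO, by amounts that varied between them. Of 30 contractile genes, 15 were higher and 0 lower (26 in the list alone; median 2.24; adjusted p = 1.2e-13, and adjusted p = 0.755 with an estimated correlation). Ckm, the creatine kinase of muscle, was 85.1 ± 61.1 FPKM against 5.32 ± 5.10. The mean log2 level of the contractile list was 1.79, 1.88 and 2.21 in wild-type libraries and 5.18, 3.07 and 4.51 in those labelled NFIA-KO. The cAMP-response list had 4 higher and 0 lower of 19 (7 in the list alone; median 0.81; adjusted p = 7.8e-05, and adjusted p = 0.755 with an estimated correlation), among them Nr4a1 (4.2 ± 0.50) and the insulin signalling adaptor Irs2 (2.70 ± 0.44). Adipocyte progenitor markers had 1 higher of 8 (adjusted p = 0.0081, and adjusted p = 0.755 with an estimated correlation). The largest changes included Irf4, a transcription factor that responds to fasting in fat (6.82 ± 0.74), and the lower lipid genes G0s2 (-5.90 ± 0.99) and Agpat2 (-4.0 ± 0.52).

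With all 6 tissue libraries, the immune, endothelial, erythroid, nerve and glia, and smooth muscle and pericyte lists were not called. Passing members were 0 of 14 immune, 0 of 13 endothelial, 0 of 8 erythroid, 1 of 6 nerve and glia, 0 of 10 smooth muscle and pericyte and 1 of 2 epidermis genes. Neither the cell cycle list (0 of 32), the interferon list (0 of 18), lipogenesis (2 of 15), cholesterol biosynthesis (2 of 19), glycolysis (3 of 17), fatty acid oxidation (3 of 23), the stress list (3 of 12), the matrix list (3 of 28), the adipogenic regulators (5 of 16) nor the myogenic regulators (2 of 6) was called. Several of these calls changed when a library was left out. Immune genes were called higher without wild-type replicate 1 (adjusted p = 0.029) or replicate 2 (adjusted p = 0.017) or 3 (adjusted p = 0.030) labelled NFIA-KO, and erythroid genes without replicate 3 so labelled (adjusted p = 0.025). Matrix genes were called higher without wild-type replicate 1 (adjusted p = 0.015) or replicate 2 labelled NFIA-KO (adjusted p = 0.0040). Without wild-type replicate 3, interferon (adjusted p = 8.0e-05), smooth muscle (adjusted p = 0.013), cell cycle (adjusted p = 0.036) and fatty acid oxidation genes (adjusted p = 0.036) were called lower. Fatty acid oxidation genes were also called lower without wild-type replicate 2 (adjusted p = 0.042) or replicate 2 labelled NFIA-KO (adjusted p = 0.019). White adipose selective genes (0 of 4) and the NFI family (0 of 4) were too few for a list test.

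In tissue 973 of 13618 genes passed, 489 higher and 484 lower (500 and 573 under quantile normalization), and the count rests on single libraries. It was 19 without wild-type replicate 1, 53 without wild-type replicate 3, 1361 without wild-type replicate 2, and 148, 109 and 541 without replicates 1, 2 and 3 labelled NFIA-KO. Adig lost its call without wild-type replicate 1. Nr4a1, Irf4 and Agpat2 lost theirs without wild-type replicate 1 or 3. Irs2 lost its call without either of those or replicate 2 labelled NFIA-KO, and Cebpa and G0s2 without either of those or replicate 1 or 2 so labelled. Ckm lost its call without any library in turn except wild-type replicate 2. With the expression filter off, 40 genes passed, and Ucp1 was no longer among them. With the muscle level of each library as a term in the fit, 2 genes passed, and Ucp1 (-1.46 ± 0.45; adjusted p = 0.66), Cox8b (-1.93 ± 0.23; adjusted p = 0.22), Asns (-1.74 ± 0.29; adjusted p = 0.46) and Btc (4.26 ± 0.75; adjusted p = 0.46) did not, with changes near those without the term and larger standard errors. All 6 tissue libraries came from the earlier run. The labels do not say whether replicates in either system are separate cultures or animals. In tissue and in C2C12 cells alike, the p-values therefore set differences only against the spread between these libraries. For C2C12 cells that spread is estimated over all 18 libraries.

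Genes that NFIA raised in cells at day 7 were lower in the libraries labelled NFIA-KO more often than chance gives. Over 12390 genes tested in both, 223 were called higher with NFIA and lower in tissue labelled NFIA-KO against 120.7 expected (odds ratio 2.85, 95% interval 2.34 to 3.47; Fisher's exact test, two-sided, p = 9.2e-26). In the opposite direction, 152 were lower with NFIA and higher in tissue against 111.5 expected (odds ratio 1.59; p = 1.1e-05, Fisher's exact test). The call on this overlap ended, with fewer tissue genes called, without wild-type replicate 1 (odds ratio 1.42; p = 0.65, Fisher's exact test) or 3 (2.26; p = 0.10), or without replicate 3 labelled NFIA-KO (1.13; p = 0.38). In the same direction, 133 were higher in both against 117.4 expected (odds ratio 1.20; p = 0.087, Fisher's exact test) and 49 lower in both against 114.6 expected (odds ratio 0.346; p = 4.3e-15, Fisher's exact test). Across all genes tested in both, the changes correlated weakly (Pearson's r -0.17, Spearman's rho -0.17). The 1132 genes raised at least 2-fold at day 7 had a median log2 fold change of -0.14 in tissue (camera p = 0.014, and p = 0.28 with an estimated correlation), with p = 0.053 without replicate 3 labelled NFIA-KO. The 1281 genes lowered at least 2-fold had a median of 0.13 (camera p = 2.3e-04, and p = 0.35 with an estimated correlation), with p = 0.074 without wild-type replicate 3. Genes are not independent replicates, so these p-values overstate the evidence from 3 libraries per group.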

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

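The tests of handling, food intake, dilution, muscle carry-over, scaling and a shared cAMP-type response were chosen after the result was seen, while the splits of the libraries and the test of Nfia dose were not.

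The effect of NFIA differed between day 0 and day 7 for 6505 genes in the interaction test. Among the 9 genes named in every main comparison the terms were 0.92 for Nfia (adjusted p = 0.015), 5.40 for Cidea (adjusted p = 2.4e-14), 1.71 for Ppargc1a (adjusted p = 1.1e-08), 2.75 for Pparg (adjusted p = 8.2e-11), 8.03 for Adipoq (adjusted p = 1.3e-15) and 10.95 for Fabp4 (adjusted p = 3.5e-10). The response to forskolin differed between NFIA and control cells for 2890 genes. Those terms were 1.37 for Nfia (adjusted p = 0.0029), 1.99 for Ucp1 (adjusted p = 2.9e-08), 3.06 for Ppargc1a (adjusted p = 2.4e-10), 0.66 for Pparg (adjusted p = 0.0011) and -0.58 for Adipoq (adjusted p = 0.0028). Ucp1 was listed at 0 in all control libraries at day 7, so its term depends on the pseudocount.

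In each comparison of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes as were called, and 10 splits are too few for a share under 0.05. The real and highest other counts were 3036 and 1 for NFIA at day 0, 7962 and 1 at day 7, and 8845 and 2 with forskolin. They were 7013 and 1 for day 7 against day 0 in control cells and 8163 and 0 in NFIA cells. Forskolin gave 570 and 2 in control cells and 4681 and 3 in NFIA cells, and tissue 973 and 6. For the interactions, NFIA and control were reassigned in 100 splits, separately at each day or with and without forskolin. As many genes were called in 1 split, the real one, for the day interaction (highest other 6170, in a split that kept the real NFIA grouping at 1 of the days). For the forskolin interaction it was 10 splits (highest other 6666), a share not under 0.05. The other 9 of these 10 all kept the real NFIA grouping either with or without forskolin, as 20 of the 100 splits did, and so carry the NFIA effect rather than chance. The 79 splits that mixed it on both sides called at most 1 gene in either interaction. Mixing moves the NFIA effect itself into the spread within groups, so these splits cannot exclude chance for either interaction.

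More genes responded to forskolin in NFIA cells than in control cells, 4681 against 570, or 6992 against 1343 with run date as a term. A scaling difference of the forskolin libraries is argued against only as the source of the number of interaction calls, since the fewest under both rescalings were 2564. Its part in single genes and directions stays open. Under quantile normalization 2159 of the 2890 genes were called again, and 1165 called terms were positive and 1399 negative. The higher Nfia level under forskolin stays open. Genes raised at least 2-fold by NFIA at day 0 had a positive median of 0.05 in the interaction (camera p = 0.037, and p = 0.48 with an estimated correlation), but the median of genes lowered by NFIA was positive as well, not negative (0.0985; camera p = 0.0042, and p = 0.27 with an estimated correlation).

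In the libraries labelled NFIA-KO, 5 of 24 brown adipocyte genes were called lower, though the list was not, and 15 of 30 contractile genes higher. For the lists, dilution of all adipocyte RNA by muscle RNA stays open. The general adipocyte list without Fabp4 had a median of -0.31 with a spread of 0.943 over 22 genes, near the -0.39 of the brown adipocyte list. A single dilution factor would lower all adipocyte genes alike. Ucp1 (-1.73 ± 0.21) and Cox8b (-2.09 ± 0.11) fell further than Adipoq (-0.24 ± 0.12) and Pparg (0.16 ± 0.30). This argues against dilution alone for Ucp1 and Cox8b. Skeletal muscle carried over in dissection stays open. Between replicates 1 and 2 labelled NFIA-KO the contractile genes shifted by 2.12 with an SD of 0.648 over genes, as carry-over could give, and between replicates 3 and 2 by 1.44 with an SD of 0.514. Carry-over should raise the myogenic regulators that muscle expresses as well, and that list was not called in tissue. A rise of muscle genes within the tissue cells was not tested and stays open as well.

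Of 379 genes that forskolin raised at least 2-fold in NFIA cells, without the fixed cAMP and stress lists, 45 were called higher and 17 lower in the libraries labelled NFIA-KO. Their median was 0.10 (camera p = 0.038, and p = 0.50 with an estimated correlation). The score of these genes was 0.343, 0.0714 and -0.12 in the 3 libraries labelled NFIA-KO and -0.078, -0.082 and -0.13 in wild-type tissue, with replicate 3 labelled NFIA-KO inside the wild-type range, so the difference rests mainly on replicate 1, and a shared cAMP-type response stays open. Stress during dissection or RNA handling stays open, with a median of 0.48 and a spread of 0.476 over 6 tested immediate early and heat shock genes. Less food intake stays open too: the lipogenesis list had a median of -0.029 with a spread of 0.4596, and 1 member was called higher and 1 lower.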

How the results depend on the processing

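Run date as a term, zeros as missing, protein-coding genes only and the muscle term were chosen after seeing the data. Counts of called genes stayed within 1.5 times of those reported under a pseudocount of 0.1, quantile normalization, median-of-ratios rescaling, no variance trend, zeros as missing and protein-coding genes only, in all 10 comparisons.

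A 2-fold minimum, which by construction removes small changes, left 703 genes for NFIA at day 0, 3212 at day 7, 3746 with forskolin, 1834 and 3200 for day 7 against day 0 in control and NFIA cells, 70 and 658 for forskolin in control and NFIA cells, 3091 and 661 for the day and forskolin interactions, and 466 in tissue. With only the groups compared, 1872 genes passed at day 0 and 239 for forskolin in control cells, from fewer libraries to estimate the spread.

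With a replicate block, 5159 genes passed for NFIA at day 0, 1260 for forskolin in control cells, 5041 for the forskolin interaction and 799 in tissue, of which 626 were among the 973. In C2C12 cells the block sets the unnumbered libraries apart, so it includes the run date, and its higher counts there are no sign of pairing. Whether the numbers pair samples stays open. Residuals of libraries with the same number correlated at -0.11 to 0.138, with a median of 0.013, over 30 pairs of numbered C2C12 libraries. With the unnumbered library left out, the residuals within a group mirror each other, so these pairs are not independent. The 3 tissue pairs correlated at -0.0091 to 0.143, against a median of -0.045 for tissue pairs with different numbers. The 15 pairs of unnumbered C2C12 libraries, all from the earlier run, correlated at 0.185 to 0.444. Run date as a term gave 5303, 1343 and 5149 in the same C2C12 comparisons, and the numbered libraries alone gave 4556 for the forskolin interaction.

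In tissue, 40 genes passed without the expression filter, and the cause was not tested. With the muscle term 2 passed: the change of Cox8b went from -2.09 ± 0.11 to -1.93 ± 0.23 and that of Ucp1 from -1.73 ± 0.21 to -1.46 ± 0.45, so their calls ended as the standard errors grew, the term being tied to the groups. Leaving out each library gave 19 to 1361 genes in tissue: 19, 1361 and 53 without wild-type replicates 1, 2 and 3, and 148, 109 and 541 without replicates 1, 2 and 3 labelled NFIA-KO. For forskolin in control cells it gave 361 to 447, with 363 without untreated replicate 2 and 361 without forskolin replicate 2. The overlap of genes lower with NFIA and higher in tissue had an odds ratio of 1.87 without the filter (p = 0.18, Fisher's exact test) and 1.13 to 5.95 without each tissue library. It was no longer called without wild-type replicate 1 (1.42) or 3 (2.26) or replicate 3 labelled NFIA-KO (1.13). The medians of the day 7 sets in tissue ranged from -0.18 to -0.11 for the higher set and from 0.041 to 0.178 for the lower set. The call ended for the higher set without replicate 3 labelled NFIA-KO (-0.14) and for the lower set without wild-type replicate 3 (0.041). The cause was not tested.

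Of 201 list tests, 95 were called, 41 with an estimated correlation, 133 with fry, 99 under quantile normalization and 94 with the block. Direction changed in 5 of the 201 with fry, 15 under quantile normalization, 4 with the block and 0 with an estimated correlation, and 1, 3, 0 and 0 of these were called in either setting.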

Other observations

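The acute phase, peroxisome and clock lists and their tests were chosen after the data were seen, as were the genes named here, and the test of a fasting-type response was written before its list's values were seen.

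At day 7, NFIA cells were higher in 10 and lower in 3 of 13 acute phase and complement genes (median 2.71; adjusted p = 3.4e-05, and adjusted p = 0.0055 with an estimated correlation). Lcn2 read 316.9 ± 46.9 FPKM and C4b 229.5 ± 15.6, against 0.0367 and 0.0833 in control cells, while Cp fell by 1.87 ± 0.15. In the libraries labelled NFIA-KO this list was called higher too, with 2 higher and 0 lower of 15 (median 0.35; adjusted p = 0.013, and adjusted p = 0.67 with an estimated correlation). That tissue call ended without wild-type replicate 3 (adjusted p = 0.052) or replicate 1 labelled NFIA-KO (adjusted p = 0.35). In NFIA cells at day 7, peroxisome genes were higher in 15 and lower in 1 of 18 (median 1.19; adjusted p = 8.0e-06, and adjusted p = 0.061 with an estimated correlation), among them catalase (Cat; 3.75 ± 0.06). With forskolin in control cells, 4 of 16 circadian clock genes were higher (median 0.21; adjusted p = 4.1e-05, and adjusted p = 0.024 with an estimated correlation). Among them was Per1 (0.68 ± 0.10), which is also in the cAMP-response list. With forskolin in NFIA cells, 8 of 16 were higher and 4 lower (adjusted p = 0.016, and adjusted p = 0.15 with an estimated correlation).

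The mitochondrially encoded mRNA mt-Nd1 read 4510.8, 4147.6 and 3864.7 FPKM in control libraries at day 7 and 14759, 10877 and 12136 in NFIA libraries. It was listed at 0 in all 6 tissue libraries, and mt-Nd2 in the 3 wild-type tissue libraries only, so neither is interpreted in tissue. The expression filter kept mt-Nd2 in the tissue fit, and 1 of the 973 genes called there has zeros of this kind.

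Pdk4, Irs2, Ddit4 and Zbtb16 were higher in the libraries labelled NFIA-KO, and a fasting-type hormone response through glucocorticoids and FOXO factors may be behind this. Over 18 other targets the median was 0.75 with a spread of 0.777, and 1 passed on its own. The list was called (adjusted p = 0.013) but not with an estimated correlation (adjusted p = 0.67), nor without wild-type replicate 3 (adjusted p = 0.052) or replicate 1 labelled NFIA-KO (adjusted p = 0.24). In NFIA cells at day 7, 14 of 18 tested members of this list were higher and 3 lower than in control cells. The list was called there (median 1.10; adjusted p = 4.9e-05, and adjusted p = 0.0055 with an estimated correlation). A rise of this list thus also occurs in culture and is no sign of fasting by itself. The hypothesis stays open.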
